A study of Mus musculus with 20 samples.

How the data were processed

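Liver RNA was measured in 20 male ob/ob mice, which lack leptin and become obese, on 20 single-channel expression arrays, 1 per mouse. The labels give 4 groups of 5 mice: filtered air, metformin in the drinking water, PM2.5 (fine airborne particles, breathed in a chamber for 6 hours per day), and PM2.5 together with metformin, called the combined group here. All mice were killed after 2 weeks. Mice are numbered here within each group in the order of the deposited samples, so that equal numbers pair no mice. The labels give no pairing, litter, batch or collection time. The label of the metformin group names no air, and these mice are treated here as mice without PM2.5. Chamber hours are given only for the groups with PM2.5, so particles and any difference in chamber stay cannot be told apart.

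The authors deposited log2 signal per probe set, made with Affymetrix Expression Console, whose version and summary method are not stated. The deposited log2 values ran from 1.55 to 19.03, and the array medians of the non-control probe sets lay between 4.77 and 4.92. The series text names another array type than the one to which the probe set identifiers belong, so genes were taken from the annotation that holds these identifiers. Of 28846 probe sets, 6640 were controls and were left out of the gene tests. Of the other 22206, 19572 were assigned to 1 gene, 0 to several and 2634 to none. All 19572 symbols matched the RefSeq symbol of their Entrez identifier. The probe sets covered 19505 genes, and for the 55 genes with several probe sets the one with the highest mean over all arrays was used. Genes whose mean signal was at or below the 40th percentile (log2 4.05) were left out as dim, which left 11844 genes tested. That level lies below the mean negative-control median of 4.49, so genes at background level could be among those tested. Arrays give no read depth, so their number limits the precision.

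Differences between groups were estimated with limma 3.58.1 in R 4.3.3, as 1 linear model of 4 group means with eBayes (prior degrees of freedom 5.68, residual degrees of freedom 16). The model takes 1 residual variance per gene over all 4 groups. Standard errors and p can therefore be too small where a compared group varies more than the others. A gene is said to rise or fall where its Benjamini-Hochberg adjusted p over the 11844 genes was under 0.05. All limma tests were two-sided. There were 5 comparisons: PM2.5 against filtered air, metformin against filtered air, the combined group against PM2.5, the combined group against metformin, and the interaction. The interaction is the metformin difference under PM2.5 minus the metformin difference without PM2.5. Errors written with ± are standard errors of a log2 difference unless SD is given.

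There were 41 gene lists, written from general knowledge: pathways of metabolism, stress and immunity, and markers of the cell types a liver piece can hold. Of 839 list entries, 178 were not tested because they were dim or not on the array, and 40 lists kept at least 5 tested members. Lists were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the 40 lists within a comparison. Calls with a correlation estimated for each list, and with fry, were made as alternatives. Counts adjusted over the list alone use only the members of that list.

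Genes are named by a rule. In each of the 4 comparisons between groups it takes the 5 largest rises and the 5 largest falls among genes that passed. It adds up to 3 members with the lowest p of each called list, limited to the 8 lists with the lowest p, and a fixed set of genes of metabolism and stress where these were tested. For the interaction it takes the 5 largest differences that passed. Predicted genes and those with provisional names were passed over among the largest changes. Genes named outside the rule are said to be chosen after their values were seen. The groups, the comparisons, the tests, the lists and the naming rule were fixed before the data were examined.

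Signals of control probe sets were compared between groups with two-sided exact permutation tests of the difference in means (252 splits of 10 arrays), adjusted first over 16 tests. The combined group against filtered air was added as a further comparison after the data were seen, which made 20 tests. The correlation of fold changes between comparisons was taken across genes, which are not independent replicates, and set beside 100 simulated data sets with no effect and beside values computed with the shared arrays split.

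The alternatives were no filter, a filter at the 60th percentile, quantile normalization, median centring, the mean of a gene's probe sets, all probe sets, array weights, eBayes with trend and robust options, a fold change of at least 1.5, fits of the compared arrays alone, and leaving out each mouse in turn. The median signal of the negative-control probe sets as a covariate, leaving out arrays 2 and 4 of the combined group, and leaving out every pair of that group's arrays were added after the data were seen. A covariate of 3' against 5' control signal, leaving out cross-hybridizing probe sets by their name ending, and a pseudocount were meant to be tried but did not apply to this array and scale. In data simulated at this size, the model recovered 17 of 67 genes shifted by 0.5 (25.4%), 59 of 67 shifted by 1 (88.1%) and 66 of 66 shifted by 2 (100%) on the log2 scale. It made 6 false calls among 148 (4.05%) and 0 sign errors. A simulated list shift of 0.5 was called with a camera adjusted p of 2.52e-30, and 0 of the 40 other lists were. The simulated genes varied independently of each other. The simulation therefore does not show how often lists whose genes vary together are called at the preset correlation.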

Results

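Gene expression was measured in the livers of 20 obese, leptin-deficient mice, 5 in each of 4 groups. The groups had filtered air, metformin, PM2.5, or PM2.5 with metformin for 2 weeks. Each value is a log2 signal from 1 array per mouse. Within groups, arrays correlated across genes at 0.9893 to 0.994 in filtered air, 0.9853 to 0.9924 with metformin, 0.9878 to 0.9932 with PM2.5 and 0.9723 to 0.9931 in the combined group. The median of the tested genes' means was 7.81, against a mean negative-control median of 4.49, and 44% of tested genes lay above 8.36, the mean 95th percentile of the negative controls. Every gene named here was read by 1 probe set.

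The comparison of PM2.5 with filtered air asks what differed in the liver with PM2.5 exposure in mice without metformin. Particles and any difference in chamber stay cannot be told apart here. Several genes of fat synthesis fell, 6 of 20 in the lipogenesis list. Fasn, the fatty acid synthase, fell by 1.89 ± 0.45 on the log2 scale (adjusted p = 0.018, limma, n = 5 mice per group). Pnpla3, a lipid droplet protein of the liver, fell by 3.03 ± 0.43 (adjusted p = 0.000785, 8.18-fold). Its signals in PM2.5 mice 1 and 2, 4.35 and 3.83, lay below the mean negative-control median of 4.49, so the floor limits its fall. Angptl8, a secreted regulator of lipoprotein lipase that is induced by feeding, had the largest fall, -3.19 ± 0.39 (adjusted p = 0.000125, 9.13-fold). Angptl4, a secreted inhibitor of the same lipase, rose from 12.13 ± 0.68 to 14.59 ± 0.17 (SD, n = 5), a log2 difference of 2.46 ± 0.38 (adjusted p = 0.00138). Cdkn1a, which encodes the cell cycle inhibitor p21, had the largest rise, 23-fold, from 6.54 ± 1.10 to 11.07 ± 1.49 (SD, n = 5; adjusted p = 0.00662, limma). The filtered-air mean of Cdkn1a lies below 8.36, the mean 95th percentile of the negative controls, so background may affect the size of its rise. For Fasn, Pnpla3, Angptl4 and Cdkn1a, 5 of 5 PM2.5 mice lay beyond every filtered-air mouse.

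Of the 20 tested genes of de novo lipogenesis, 6 fell, 0 rose and 14 did not pass. Adjusted over the list alone 11 fell. The list median was -0.76 (camera adjusted p = 7.63e-07; adjusted p = 0.437 with an estimated correlation). Aacs, which activates acetoacetate for lipid synthesis, fell by 2.35 ± 0.20 (adjusted p = 6.31e-07). Gpam, the mitochondrial enzyme that begins triglyceride assembly, fell by 1.10 ± 0.23 (adjusted p = 0.00797). Mid1ip1, an activator of acetyl-CoA carboxylase, fell by 2.68 ± 0.42 (adjusted p = 0.00138) to 4.64 ± 0.58 (SD), close to the mean negative-control median of 4.49, so the floor of the signal limits its fall. Of 19 cholesterol synthesis genes 1 passed, also when adjusted over the list alone: Mvd, an enzyme of the mevalonate pathway, fell by 2.05 ± 0.43 (adjusted p = 0.00868). The list median was -0.63 (camera adjusted p = 0.00184; adjusted p = 0.763 with an estimated correlation). Stard4 at -1.12 (adjusted p = 0.0977) and Sc5d at -0.50 (adjusted p = 0.122) did not pass. Mitochondrial complex I genes had a median of -0.29 (camera adjusted p = 3.74e-05; adjusted p = 0.437 with an estimated correlation). Of these 36 genes 1 fell, Ndufa2 (-0.80 ± 0.21, adjusted p = 0.0297), and 1 adjusted over the list alone. Complexes II to V had a median of -0.20 (camera adjusted p = 5.99e-05; adjusted p = 0.552 with an estimated correlation). Of these 39 genes Sdhd (-0.46 ± 0.13, adjusted p = 0.0442) and Atp5j2 (-0.47 ± 0.14, adjusted p = 0.0484) fell, and 5 adjusted over the list alone. With the negative-control covariate Atp5j2 did not pass (-0.46, adjusted p = 0.0547). Ndufb2, Ndufs1 and Uqcrh were at -0.56, -0.43 and -0.59 and did not pass (adjusted p = 0.0634, 0.0753 and 0.0613). Heat shock genes had a median of -0.46 (camera adjusted p = 0.0256; adjusted p = 0.437 with an estimated correlation). Of these 10 genes 1 fell, the mitochondrial chaperonin Hspe1 (-0.55, adjusted p = 0.0477; named after its value was seen), and 2 adjusted over the list alone.

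Glucocorticoid targets moved the other way: 6 of 14 rose, 0 fell and 8 did not pass. Adjusted over the list alone 8 rose, and all 14 had values above 0. Their median was 1.23 (camera adjusted p = 1.58e-07; adjusted p = 0.0834 with an estimated correlation), and 7 of the 14 also stand in other lists. Besides Angptl4 and Cdkn1a they included Sgk1, a serum- and glucocorticoid-induced kinase (1.22 ± 0.20, adjusted p = 0.00195), and Pck1, the enzyme that commits carbon to glucose synthesis (1.26 ± 0.20, adjusted p = 0.00192). Among 16 gluconeogenesis genes, Pck1 and the transcription factor Foxo1 (0.80 ± 0.22, adjusted p = 0.0375) rose, and 5 rose adjusted over the list alone. Sik1 was at 0.83 (adjusted p = 0.0669), and the list median was 0.44 (camera adjusted p = 0.00208; adjusted p = 0.437 with an estimated correlation). Of 35 genes of PPAR-alpha and fatty acid oxidation 5 rose, 7 adjusted over the list alone, with a median of 0.19 (camera adjusted p = 0.00184; adjusted p = 0.763 with an estimated correlation). They included Cpt1a, the carrier that admits fatty acids to mitochondria (1.08 ± 0.23, adjusted p = 0.00991), Pdk4, a brake on glucose oxidation (1.66 ± 0.41, adjusted p = 0.0211), and Creb3l3, a liver transcription factor (0.66 ± 0.16, adjusted p = 0.0198). The metal-binding metallothioneins Mt1 and Mt2 rose by 2.03 ± 0.36 (adjusted p = 0.00276) and 3.08 ± 0.60 (adjusted p = 0.00525). The zinc exporter Slc30a1 rose by 0.76 ± 0.18 (adjusted p = 0.0176). These were the 3 of 6 genes of the metallothionein list that passed, and 3 rose adjusted over the list alone. The list median was 0.73 (camera adjusted p = 0.00788; adjusted p = 0.103 with an estimated correlation). The lipid droplet coat gene Plin4 rose by 2.25 ± 0.37 (adjusted p = 0.00196) and the cold-inducible RNA-binding gene Cirbp by 2.28 ± 0.41 (adjusted p = 0.0034). The filtered-air mean of Plin4, 4.56 ± 0.48 (SD), is close to the mean negative-control median of 4.49, so the size of its rise is not measured. Anks4b (-2.55 ± 0.24, adjusted p = 2.7e-06) and A4gnt (-2.49 ± 0.35, adjusted p = 0.000785) were the other two of the 5 largest falls. The PM2.5 mean of A4gnt, 3.75, lies below the mean negative-control median of 4.49, so the size of its fall is not measured.

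**Figure D1:**
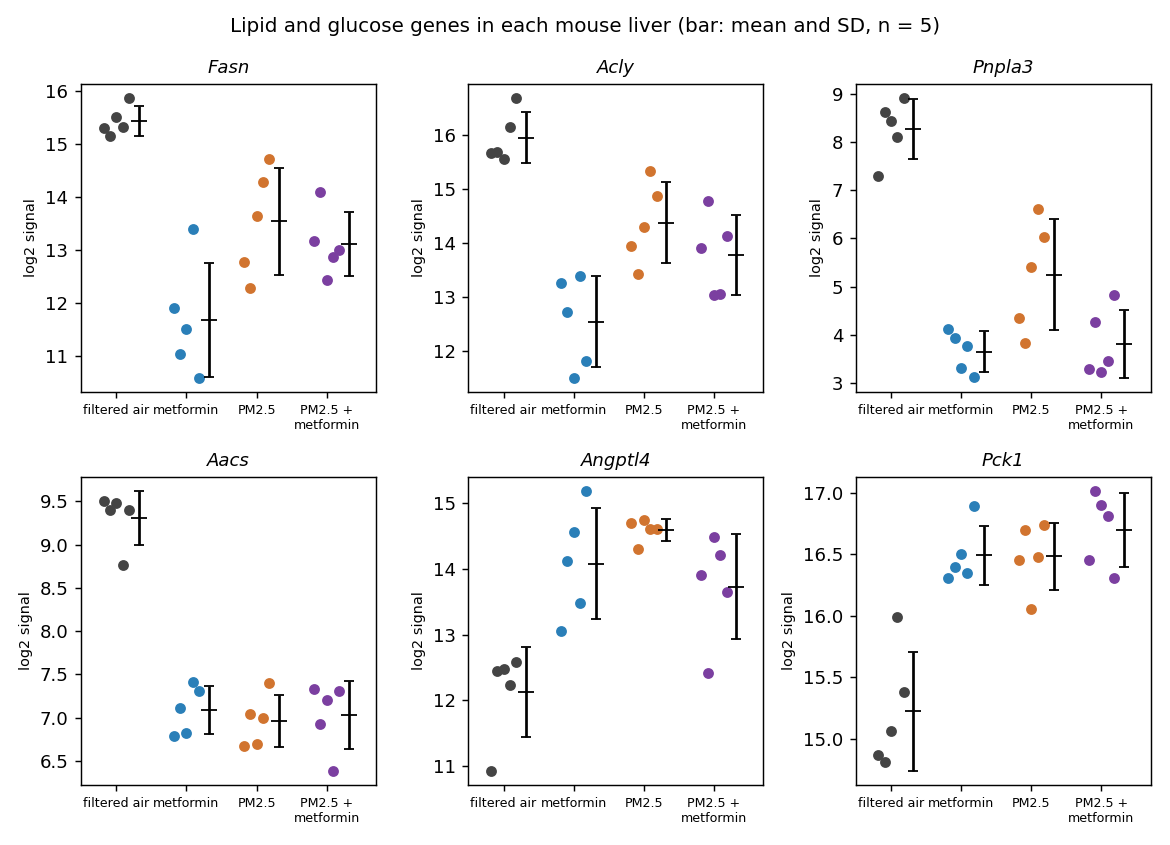
Log2 signal (y axis) of the lipid genes Fasn, Acly, Pnpla3, Aacs and Angptl4 and of Pck1 in each mouse (dots) by group (x axis), with bars for the mean and SD of 5 mice. For all 6 genes the 5 PM2.5 mice and the 5 metformin mice lie beyond every filtered-air mouse.

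Markers of other cells were higher as lists with PM2.5, with few members passing. Of 26 Kupffer cell and macrophage markers 0 passed in limma, also adjusted over the list alone. Of these, 23 lay above 0, with a median of 0.40 (camera adjusted p = 0.0202; adjusted p = 0.816 with an estimated correlation). This call was lost without filtered-air mouse 5 (adjusted p = 0.0812) or PM2.5 mouse 4 (adjusted p = 0.198). Among 16 endothelial markers 1 rose, also adjusted over the list alone, with a median of 0.31 (camera adjusted p = 0.0256; adjusted p = 0.737 with an estimated correlation). This list call was lost without filtered-air mouse 5 (adjusted p = 0.11), PM2.5 mouse 4 (adjusted p = 0.0566) or PM2.5 mouse 5 (adjusted p = 0.0551). Markers of stellate cells (median 0.09, camera adjusted p = 0.815), neutrophils (0.04, adjusted p = 0.815) and T and NK cells (0.39, adjusted p = 0.5) were not called. The neutrophil and the T and NK markers were dim. The medians of their mean signals, 5.16 and 4.78, lay near the mean negative-control median of 4.49, so these lists could show little. Lists often examined for inhaled particles were not called either. The inflammatory cytokine genes among them were dim too, with a median of the mean signals of 5.31, so their lack of a call says little. The 6 tested aryl hydrocarbon receptor targets had a median of 0.09, a mean of -0.08 and 1 member lower (camera adjusted p = 0.815, direction down). Only these 6 of the 10 listed targets were tested, and Cyp1a1 was not, so the lack of a call says little about this receptor. The 25 NRF2 targets had a median of 0.18 and 0 members passing in limma (camera adjusted p = 0.239). Medians were 0.26 for 13 inflammatory cytokine and NF-kappaB genes (1 rose; camera adjusted p = 0.115), 0.11 for 25 acute-phase genes (2 rose; adjusted p = 0.139) and -0.24 for 26 interferon-induced genes (0 passed in limma; adjusted p = 0.11). The 12 p53 targets, of which Cdkn1a rose, had a median of -0.05 and a mean of 0.30 and were not called (camera adjusted p = 0.842, direction down).

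In limma 612 genes differed between PM2.5 and filtered air, 316 higher and 296 lower, and 508 of them by at least 1.5-fold. Of these genes 51.6% were higher, but 46.2% of those called after quantile normalization and 42.5% after median centring, so the balance of rises and falls depends on the scaling. The fixed genes that did not pass numbered 7, from -0.80 to 1.06 (lowest adjusted p = 0.212). Of the 40 lists 6 were called higher and 5 lower, 0 with an estimated correlation and 8 with fry. The 29 others had adjusted p from 0.0527 to 0.996. The count was 208 without PM2.5 mouse 2, 248 without PM2.5 mouse 5, and 268, 377 and 372 without filtered-air mice 1, 2 and 3. Of 25 named genes that passed, 18 passed without any 1 mouse. Without PM2.5 mouse 2 the adjusted p of Fasn, Pdk4, Creb3l3, Foxo1, Ndufa2, Sdhd and Atp5j2 lay between 0.0749 and 0.162. Apart from Fasn these were also lost without other mice. This held for Creb3l3 without filtered-air mouse 1 (0.0531) or PM2.5 mouse 5 (0.0545), Pdk4 without filtered-air mouse 3 (0.053) or PM2.5 mouse 5 (0.0675), and Foxo1, Ndufa2, Sdhd and Atp5j2 without several others (0.0979 to 0.133 without PM2.5 mouse 5 or filtered-air mouse 1).

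The comparison of metformin with filtered air gives the response to the drug without particles. Of the genes of fat synthesis 13 of 20 fell, and of those of cholesterol synthesis 6 of 19, with the lowest list medians of the 4 comparisons between groups. With an estimated correlation the first list was called (adjusted p = 0.0264) and the second was not (0.287). Pnpla3 fell to background, from 8.28 ± 0.62 to 3.65 ± 0.43 (SD; adjusted p = 2.16e-06, limma, n = 5 mice per group). Its difference of -4.62 ± 0.43 does not measure the size of the fall, since the metformin mean lies below the mean negative-control median of 4.49. Fasn fell by 3.75 ± 0.45 (adjusted p = 8.17e-05), 13.4-fold, from 15.43 ± 0.28 to 11.68 ± 1.08 (SD). Acly, which supplies cytosolic acetyl-CoA, fell by 3.41 ± 0.40 (adjusted p = 8.17e-05). Pck1 rose by 1.27 ± 0.20 (adjusted p = 0.00132), Cpt1a by 1.38 ± 0.23 (adjusted p = 0.0019) and Angptl4 by 1.94 ± 0.38 (adjusted p = 0.00708). For these 6 genes 5 of 5 metformin mice lay beyond every filtered-air mouse.

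Of the 20 lipogenesis genes 13 fell, 0 rose and 7 did not pass; adjusted over the list alone 18 fell. The median was -1.60, and this list was called with the preset and with the estimated correlation (camera adjusted p = 3.96e-26; adjusted p = 0.0264 with an estimated correlation). Aacs fell by 2.22 ± 0.20 (adjusted p = 1.83e-06). Fabp5, a fatty acid binding protein outside that list, fell by 3.38 ± 0.51 (adjusted p = 0.000717). Of 19 cholesterol synthesis genes 6 fell and 13 did not pass, and 16 fell adjusted over the list alone. The median was -1.42 (camera adjusted p = 5.7e-13; adjusted p = 0.287 with an estimated correlation). The mevalonate pathway enzymes Mvd, Pmvk and Fdps fell, with differences of -2.38 ± 0.43, -2.35 ± 0.48 and -2.64 ± 0.56 (adjusted p = 0.00368, 0.00967 and 0.013). The spread of this list was wide, with mean deviations of single metformin mice from -1.97 to 0.81. Glycolysis and glycogen genes had a median of -0.16 with 2 of 18 lower and 4 adjusted over the list alone (camera adjusted p = 0.0224; adjusted p = 0.4 with an estimated correlation). This call was lost without filtered-air mouse 4 (adjusted p = 0.0605) or metformin mouse 2 (adjusted p = 0.0881). Pdzk1ip1 fell by 3.60 ± 0.62 (adjusted p = 0.00256).

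Some chaperones of the endoplasmic reticulum were higher with metformin: 4 of 19 unfolded protein response genes rose, and 6 adjusted over the list alone. Their median was 0.37 (camera adjusted p = 1.25e-06; adjusted p = 0.371 with an estimated correlation). Herpud1, which serves protein degradation at the endoplasmic reticulum, rose by 1.13 ± 0.17 (adjusted p = 0.000695). The disulfide isomerase Pdia3 rose by 0.83 ± 0.18 (adjusted p = 0.0175) and the chaperone Calr by 0.83 ± 0.19 (adjusted p = 0.0213). The mean deviation of this list in single metformin mice ran from -0.25 to 1.06. Glucocorticoid targets had a median of 0.70 with 4 of 14 higher, 5 adjusted over the list alone (camera adjusted p = 0.000131; adjusted p = 0.256 with an estimated correlation). Among them was Zbtb16, a transcription factor (1.86 ± 0.41, adjusted p = 0.0173). Of 25 acute-phase genes 2 rose, 6 adjusted over the list alone, with a median of 0.18 (camera adjusted p = 0.000131; adjusted p = 0.4 with an estimated correlation). The interleukin-6 receptor gene Il6ra rose by 1.58 ± 0.29 (adjusted p = 0.00479). Lrg1, a secreted glycoprotein, rose by 2.18 ± 0.49 (adjusted p = 0.0179), and the deubiquitinase gene Usp2 rose from background, 4.12 ± 0.41, to 6.46 ± 0.42 (SD; adjusted p = 0.0034). Its difference of 2.34 ± 0.42 starts from a mean below the negative-control median of 4.49, so the size of the rise is not measured. PPAR-alpha and fatty acid oxidation genes had a median of 0.24 with 3 of 35 higher, and 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000177; adjusted p = 0.483 with an estimated correlation). Gluconeogenesis genes had a median of 0.21 with 2 of 16 higher and 5 adjusted over the list alone (camera adjusted p = 0.0196; adjusted p = 0.4 with an estimated correlation). This list call was lost without filtered-air mouse 2 (adjusted p = 0.101).

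Several housekeeping lists were lower by small amounts. Complex I genes had a median of -0.29 (1 of 36 fell, 11 adjusted over the list alone; camera adjusted p = 2.24e-08; adjusted p = 0.287 with an estimated correlation). Complexes II to V had a median of -0.23 (1 of 39 fell, 0 adjusted over the list alone; camera adjusted p = 5.9e-05; adjusted p = 0.4 with an estimated correlation). Cytosolic ribosomal proteins had a median of -0.22 (1 of 37 fell, 1 adjusted over the list alone; camera adjusted p = 1.88e-05; adjusted p = 0.4 with an estimated correlation). Ndufb3 (-0.51 ± 0.14, adjusted p = 0.045), Uqcr10 (-0.71 ± 0.19, adjusted p = 0.047) and Rpl37 (-0.62 ± 0.14, adjusted p = 0.019) were the members that passed. Ndufa5, Ndufa12, Cox5b, Atp5l, Rps24 and Rps20, from -0.31 to -0.51, did not (adjusted p = 0.0711 to 0.224). Of 18 cell cycle genes 2 fell, 9 adjusted over the list alone, with a median of -0.53 (camera adjusted p = 7.21e-05; adjusted p = 0.256 with an estimated correlation). They were Tyms, which makes thymidylate (-0.61 ± 0.15, adjusted p = 0.025), and the replication helicase gene Mcm3 (-0.74 ± 0.19, adjusted p = 0.0329). Mcm6 was at -0.64 (adjusted p = 0.0634). The median of the mean signals of the cell cycle list was 5.01, close to the mean negative-control median of 4.49, so the floor limits its change. NRF2 and glutathione genes had a median of -0.25, with 4 of 25 lower, and 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00356; adjusted p = 0.4 with an estimated correlation; 0.0667 without metformin mouse 2). The 12 p53 targets had a median of -0.26 with 0 passing in limma and 1 above 0 (camera adjusted p = 0.0224; adjusted p = 0.287 with an estimated correlation; 0.0587 without metformin mouse 2).

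The array background also differed between these groups. The median of the negative-control probe sets was 4.50 ± 0.04 with metformin and 4.41 ± 0.03 in filtered air (SD, n = 5). The difference was 0.10 (exact permutation p = 0.00794, the smallest the 252 splits allow; adjusted p = 0.0635 over 16 tests and 0.0318 over the 20 that include an added comparison). Endothelial markers had a median of -0.25 (1 of 16 fell, 1 adjusted over the list alone; camera adjusted p = 0.00629; adjusted p = 0.4 with an estimated correlation). Stellate cell and matrix markers had a median of -0.18 (0 of 21 passed in limma, 2 above 0; camera adjusted p = 0.0335; adjusted p = 0.465 with an estimated correlation). With the negative-control median as a covariate, the calls of endothelial markers (adjusted p = 0.0802), stellate markers (0.136), p53 targets (0.0918) and gluconeogenesis (0.0741) were lost. Their medians were then -0.13, -0.14, -0.17 and 0.18, against -0.25, -0.18, -0.26 and 0.21 without the covariate. Complex I (adjusted p = 2.04e-08), complexes II to V (4.62e-05), ribosomal proteins (9.47e-05), cell cycle (5.92e-05) and NRF2 genes (0.00359) stayed called with it. The covariate did not overlap between these groups, from 4.361 to 4.432 in filtered air and from 4.452 to 4.543 with metformin. Calls can therefore be lost because it goes along with metformin, whether or not background is a cause. The stellate call was also lost without filtered-air mouse 2 (0.101) or 4 (0.0654) and without metformin mouse 2 (0.229) or 4 (0.109). Macrophage markers were not called (median -0.42, adjusted p = 0.0708), nor were aryl hydrocarbon receptor targets (median -0.30, adjusted p = 0.0729). With metformin the poly-A spikes differed by -0.255 from filtered air (exact permutation p = 0.0317, adjusted p = 0.0576 over 20 tests).

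In limma 373 genes differed, 149 higher and 224 lower, 325 of them by at least 1.5-fold. Of the lists 5 were called higher and 11 lower, 1 with an estimated correlation and 10 with fry. The 24 others had adjusted p from 0.0708 to 0.966. The fixed genes that did not pass numbered 7, from -1.02 to 2.40 (lowest adjusted p = 0.118). With the negative-control median as a covariate 147 genes were called, and Lrg1 (adjusted p = 0.0882), Pmvk (0.0511), Fdps (0.0648), Ndufb3 (0.155), Rpl37 (0.0548), Uqcr10 (0.174) and Tyms (0.0939) were not. The 373 genes kept 88% of their median change in that fit. The differences of the 7 genes were then 1.68, -1.95, -2.14, -0.42, -0.60, -0.56 and -0.54 in the same order. The count was 157 and 248 without metformin mice 3 and 4, and 161, 171, 216 and 194 without filtered-air mice 1, 2, 3 and 5. Without metformin mouse 3 the adjusted p of 9 of the 24 named genes that passed, Lrg1, Zbtb16, Ndufb3, Pdia3, Calr, Rpl37, Uqcr10, Tyms and Mcm3, lay between 0.0529 and 0.104. All but Zbtb16 and Pdia3 were also lost without a filtered-air mouse, most for Uqcr10 (0.121) and Ndufb3 (0.108) without mouse 2.

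**Figure D2:**
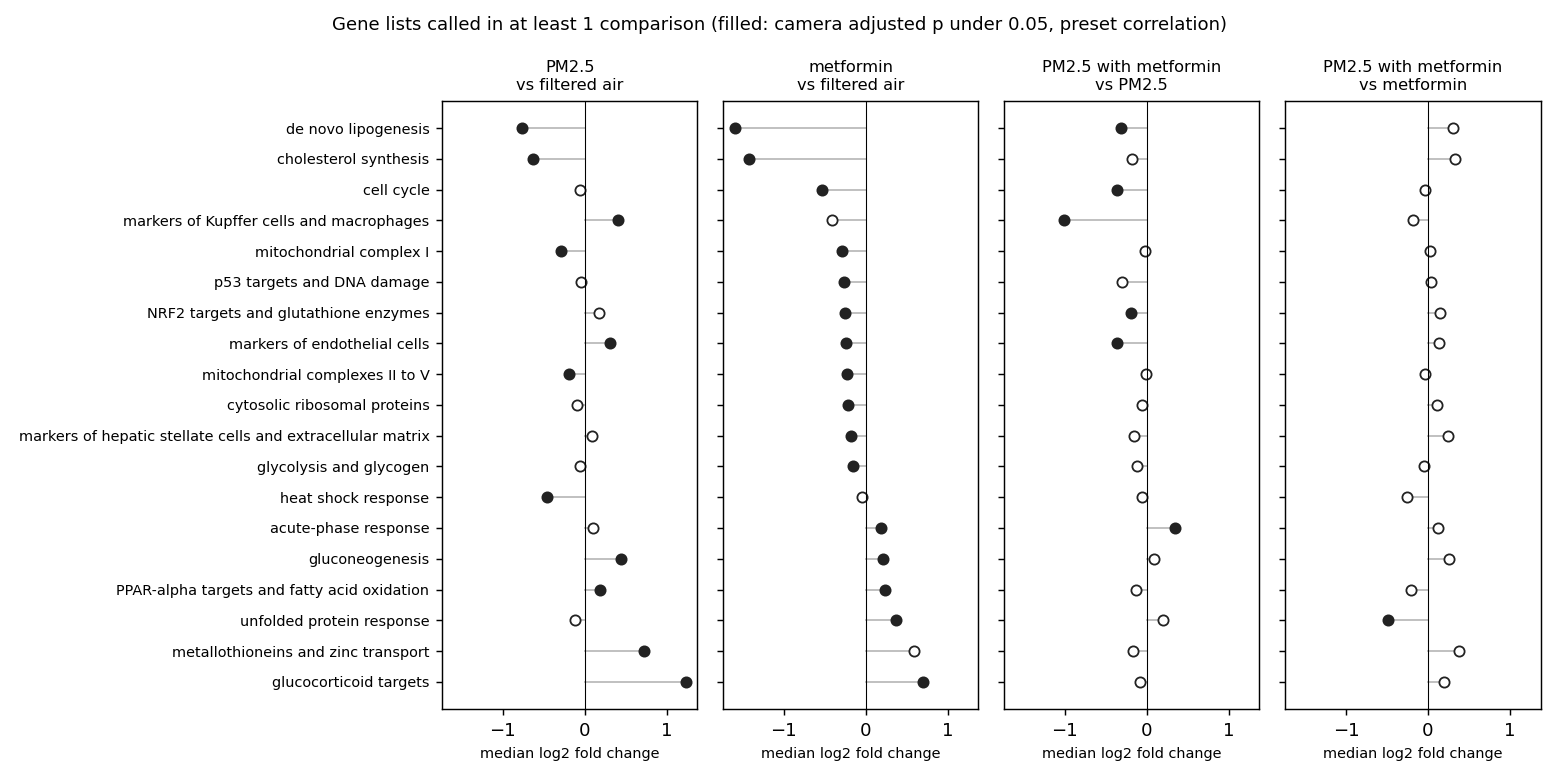
Median log2 fold change (x axis) of 19 gene lists (y axis) called in at least 1 comparison, in 4 panels for the comparisons between groups; filled points have a camera adjusted p under 0.05 at the preset correlation, open points do not. Lipogenesis lies at -0.76 with PM2.5, -1.60 with metformin, -0.31 for the combined group against PM2.5 and 0.30 against metformin.

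The comparison of the combined group with PM2.5 asks what metformin changed in mice that breathed particles. Of the macrophage markers 12 of 26 fell, and of the endothelial markers 7 of 16, with neither list called at an estimated correlation (adjusted p = 0.81 for both). Vsig4, a complement receptor of Kupffer cells, fell by 2.51 ± 0.48 (adjusted p = 0.00273, limma, n = 5 mice per group), from 13.29 ± 0.30 to 10.78 ± 1.63 (SD), and lay below every PM2.5 mouse in 4 of 5 mice. Its SD was 0.40 in filtered air and 0.19 with metformin. The variance pooled over the 4 groups is thus too small for the combined group, and so may be the standard error and p. Pdk4 had the largest fall, -2.66 ± 0.41 (adjusted p = 0.000742), from 11.05 to 8.38. Dbp, a transcription factor of the circadian output, rose by 1.89 ± 0.32 (adjusted p = 0.00153), above every PM2.5 mouse in 5 of 5. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose by 1.61 ± 0.38 (adjusted p = 0.00939), and Cpt1a by 0.78 ± 0.23 (adjusted p = 0.0334).

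Of 26 Kupffer cell and macrophage markers 12 fell, 0 rose and 14 did not pass. Adjusted over the list alone 17 fell, and the median was -1.01 (camera adjusted p = 8.59e-09; adjusted p = 0.81 with an estimated correlation). Msr1, a scavenger receptor, fell by 1.5 ± 0.29 (adjusted p = 0.00317). Adgre1, which encodes the macrophage antigen F4/80, fell by 1.47 ± 0.30 (adjusted p = 0.00482). Of 16 endothelial markers 7 fell and 9 did not pass, 7 adjusted over the list alone, with a median of -0.37 (camera adjusted p = 0.000387; adjusted p = 0.81 with an estimated correlation). The sinusoidal endothelial genes Fcgr2b, Clec4g and Oit3 fell, with differences of -1.33 ± 0.24, -1.52 ± 0.28 and -1.56 ± 0.33 (adjusted p = 0.0022, 0.00227 and 0.00525). Markers of stellate cells (median -0.15, camera adjusted p = 0.653), neutrophils (-0.08, adjusted p = 0.944), T and NK cells (-0.03, adjusted p = 0.944) and cholangiocytes (-0.46, adjusted p = 0.278) were not called. The neutrophil and the T and NK markers were dim, with medians of the mean signals of 5.16 and 4.78, so these lists could show little. Among the largest changes were also falls of Pla2g7, a phospholipase secreted by macrophages (-2.32 ± 0.44, adjusted p = 0.00268), Mr1, an antigen-presenting molecule (-2.22 ± 0.46, adjusted p = 0.00498), and Fabp7, a fatty acid binding protein (-2.14 ± 0.52, adjusted p = 0.0111). The SDs of Mr1 and Fabp7 were also wider in the combined group (1.447 and 1.677) than with PM2.5 (0.345 and 0.297).

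The array background and these markers both varied widely within the combined group. The negative-control median was 4.59 ± 0.15 there (SD, n = 5), with arrays 2 and 4 at 4.79 and 4.69, against 4.44 ± 0.07 with PM2.5. The difference was 0.15 (exact permutation p = 0.0794; adjusted p = 0.159 over 16 tests and 0.132 over 20). The positive-control median was 0.30 higher (exact permutation p = 0.00794, the smallest the splits allow; adjusted p = 0.0635 over 16 tests and 0.0318 over 20). The mean deviation of the macrophage markers was -1.44 in combined mouse 2 and 0.95 in mouse 5, with a group mean of -0.48 ± 0.89 (SD) against 0.51 ± 0.40 with PM2.5. At the preset correlation the macrophage list stayed called with the negative-control covariate (median -0.47, camera adjusted p = 0.00038) and without arrays 2 and 4 (median -0.61, adjusted p = 2.37e-06). The endothelial medians in these fits were -0.34 and -0.30. With the covariate the single genes Vsig4 (adjusted p = 0.129), Msr1 (0.142), Adgre1 (0.179), Fcgr2b (0.0891), Clec4g (0.106) and Oit3 (0.211) no longer passed, and their differences shrank to -1.47, -0.92, -0.997, -0.76, -0.95 and -0.75. Without arrays 2 and 4, Msr1 (0.0532), Adgre1 (0.08) and Oit3 (0.0938) did not, at -1.08, -1.13 and -0.93. Pla2g7, Mr1 and Fabp7 lost their calls in both fits: they were at -1.50, -1.24 and -1.01 with the covariate (adjusted p = 0.127, 0.208 and 0.362) and at -1.62, -1.50 and -1.31 without the 2 arrays (0.0532, 0.103 and 0.136).

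**Figure D3:**
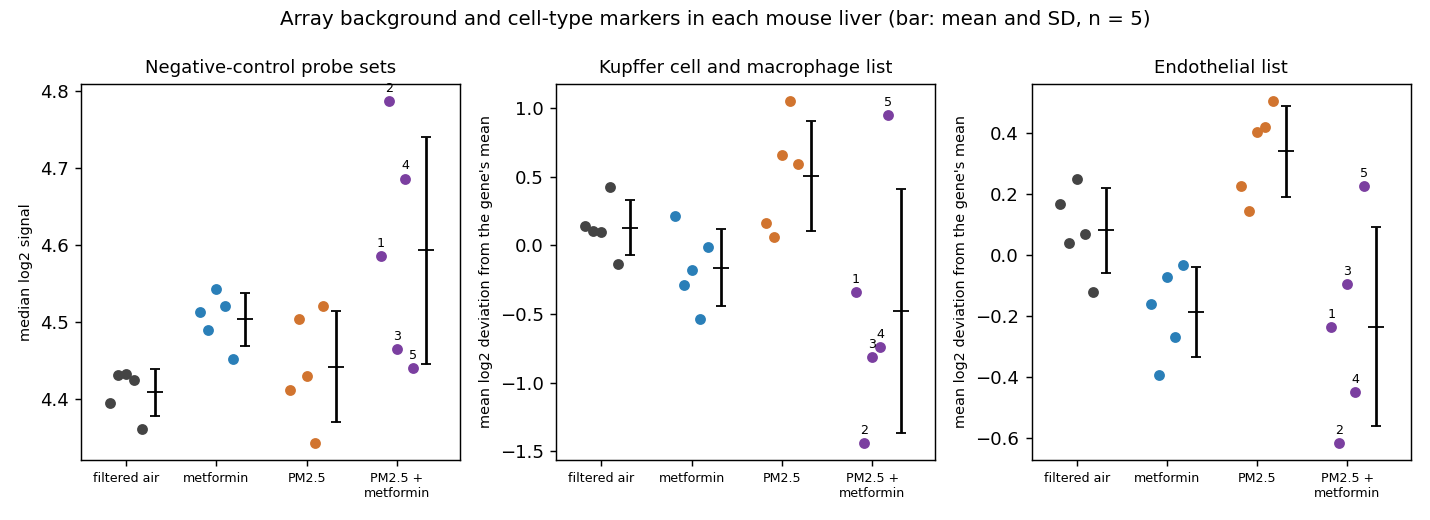
Negative-control median (log2 signal) and the mean deviation (log2) of the macrophage and the endothelial markers on the y axes, for each mouse (dots) by group (x axis), with bars for the mean and SD of 5 mice and the mice of the combined group numbered. In the combined group the negative-control median reaches 4.79 in mouse 2, and the macrophage mean runs from -1.44 in mouse 2 to 0.95 in mouse 5.

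The other called lists had higher camera adjusted p than the macrophage and endothelial markers. Of 20 lipogenesis genes 5 fell, 7 adjusted over the list alone, with a median of -0.31 (camera adjusted p = 0.0165; adjusted p = 0.866 with an estimated correlation). They included the elongase Elovl6 (-1.69 ± 0.40, adjusted p = 0.0101), the lipogenic regulator Thrsp (-0.75 ± 0.20, adjusted p = 0.0214) and Pnpla3 (-1.43 ± 0.43, adjusted p = 0.0349), whose combined mean of 3.82 lies below the mean negative-control median of 4.49. This list call was lost without PM2.5 mouse 5 (adjusted p = 0.146) or combined mouse 3 (0.0711) or 4 (0.0555), and with quantile normalization (0.0787). Of 25 NRF2 and glutathione genes 6 fell, 6 adjusted over the list alone, with a median of -0.19 (camera adjusted p = 0.0191; adjusted p = 0.866 with an estimated correlation). The glutathione transferase genes Gstm6, Gstm4 and Gstm2 fell, with differences of -0.98 ± 0.21, -0.70 ± 0.19 and -0.84 ± 0.23 (adjusted p = 0.00607, 0.0191 and 0.0214). The list call was lost without PM2.5 mouse 2 (0.0803) or 5 (0.0602) or combined mouse 4 (0.123), without arrays 2 and 4 together (median -0.13, adjusted p = 0.134) and with quantile normalization (0.0787). Of 25 acute-phase genes 1 rose and 1 fell, 1 rose adjusted over the list alone, and the median was 0.34 (camera adjusted p = 0.0332; adjusted p = 0.866 with an estimated correlation). Itih4, a plasma protease inhibitor of that response, rose by 1.28 ± 0.29 (adjusted p = 0.00817), the pentraxin Crp fell by 0.48 ± 0.15 (adjusted p = 0.0448), and Steap4 was at 0.58 (adjusted p = 0.0618). The acute-phase call was lost with the covariate (median 0.19, adjusted p = 0.347), without arrays 2 and 4 (median 0.07, adjusted p = 0.636), and without any of PM2.5 mice 1 (0.176), 3 (0.0967) and 5 (0.0736) or combined mice 2 (0.0846) and 4 (0.162). Of 18 cell cycle genes 2 fell, 3 adjusted over the list alone, with a median of -0.37 (camera adjusted p = 0.0121; adjusted p = 0.81 with an estimated correlation). These were Tyms (-0.54 ± 0.15, adjusted p = 0.0202) and the cyclin Ccna2 (-0.71 ± 0.23, adjusted p = 0.0473), and Mcm6 was at -0.57 (adjusted p = 0.0532). Both means of Ccna2, 4.29 and 3.58, lie below the mean negative-control median of 4.49, so its difference is one between background signals. The cell cycle list was dim as a whole, with a median of the mean signals of 5.01. The 5 largest rises also held the growth factor-induced gene Egr1 (1.91 ± 0.60, adjusted p = 0.0412), the receptor phosphatase Ptprf (1.81 ± 0.25, adjusted p = 0.000449), the trafficking gene Synrg (1.81 ± 0.18, adjusted p = 1.06e-05) and Lrg1 (1.79 ± 0.49, adjusted p = 0.0228).

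In limma 1383 genes differed between the combined group and PM2.5, 823 higher and 560 lower, 1019 by at least 1.5-fold. Of these 59.5% were higher, but 45.7% of the 1412 called after quantile normalization. Of the lists 1 was called higher and 5 lower, 0 with an estimated correlation and 1 with fry. The 34 others had adjusted p from 0.107 to 0.944. The fixed genes that did not pass numbered 8, from -0.56 to 1.77 (lowest adjusted p = 0.0747). The gene count was 79 with the negative-control covariate, 206 without arrays 2 and 4, and 509 with the compared arrays alone. The 1383 genes kept 68.5% of their median change with the covariate and 74.2% without the 2 arrays. It was 844 and 772 without PM2.5 mice 3 and 4, and 753, 637 and 2143 without combined mice 2, 4 and 5. The list count was 3 without PM2.5 mouse 5 or combined mouse 4 and 11 without combined mouse 5. Of 27 named genes that passed, 23 did not with the covariate and 19 did not without arrays 2 and 4. Cyp7a1 was among both (adjusted p = 0.115 and 0.0533), although its difference stayed at 1.62 and 1.68, and Dbp was lost with the covariate (1.27, adjusted p = 0.0674). Lrg1 shrank to 0.98 with the covariate (adjusted p = 0.442) and 0.99 without the 2 arrays (0.316). Crp, Gstm4, Itih4 and Ccna2 were also lost with the covariate and more than 1.5 times smaller, at -0.22, -0.44, 0.82 and -0.45, while Egr1 was larger, at 3.13 (adjusted p = 0.0134). Ptprf, Synrg and Pdk4 passed under every alternative run. Without combined mouse 4 alone, Egr1, Lrg1, Tyms, Ccna2, Thrsp, Pnpla3, Gstm4, Gstm2, Crp and Cpt1a had adjusted p from 0.0615 to 0.13. All of these but Gstm2 were also lost without at least 1 of PM2.5 mice 1, 3, 4 and 5.

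The comparison of the combined group with metformin asks what differed with PM2.5 exposure in mice on the drug. Of the genes of the unfolded protein response in the endoplasmic reticulum 9 of 19 fell, a list not called at an estimated correlation (adjusted p = 0.991). Hspa5, the main chaperone of that compartment, fell by 1.02 ± 0.22 (adjusted p = 0.00436, limma, n = 5 mice per group), Hsp90b1 fell by 0.69 ± 0.15 (adjusted p = 0.00436), and the disulfide isomerase Pdia6 fell by 1.11 ± 0.24 (adjusted p = 0.00475). Cytosolic chaperone genes were among the largest falls, with Hsph1 at -2.09 ± 0.51 (adjusted p = 0.00869) and Chordc1, a co-chaperone of Hsp90, at -1.88 ± 0.37 (adjusted p = 0.00246). Fasn rose by 1.43 ± 0.45 (adjusted p = 0.0343) and the lipid droplet gene Plin4 by 1.84 ± 0.37 (adjusted p = 0.00316). Hmox1, the heme oxygenase, rose by 1.07 ± 0.36 (adjusted p = 0.0431).

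Of 19 unfolded protein response genes 9 fell, 0 rose and 10 did not pass. Adjusted over the list alone 10 fell, and the median was -0.49 (camera adjusted p = 0.000319; adjusted p = 0.991 with an estimated correlation). It was the only list called at the preset correlation, and the 39 others had adjusted p from 0.0644 to 0.981. Creld2, another gene of this list, fell by 2.01 ± 0.55 (adjusted p = 0.0163). Its SD with metformin was 1.74, and that of Hsph1 was 1.55. The mean deviation of the list was 1.06, 0.73 and 0.82 in metformin mice 3, 4 and 5. In metformin mice 1 and 2 it was -0.02 and -0.25, within the combined range of -0.26 to 0.02. The combined mean of -0.11 lay near that of filtered air, -0.09. The fall thus reflects high values in metformin mice 3, 4 and 5. Of 10 heat shock genes 4 fell, and the list, with a median of -0.26, was not called (camera adjusted p = 0.0644). Lipogenesis (4 of 20 rose, median 0.30, camera adjusted p = 0.0644), cholesterol synthesis (3 of 19 rose, median 0.33, adjusted p = 0.0855) and immediate early genes (1 rose, median 0.54, adjusted p = 0.0644) were not called. Egr1 of that last list rose by 2.06 ± 0.60 (adjusted p = 0.0221). Macrophage markers had 2 of 26 lower and a median of -0.18 (adjusted p = 0.172), and endothelial markers 3 higher and 2 lower with a median of 0.14 and a mean of -0.05 (adjusted p = 0.889). Xpo6, a nuclear exporter of actin (1.86 ± 0.20, adjusted p = 2.84e-05), Fam25c (1.75 ± 0.38, adjusted p = 0.00464) and Synrg (1.73 ± 0.18, adjusted p = 2.27e-05) rose. Fabp7 (-2.06 ± 0.52, adjusted p = 0.0108) and the ion channel gene Asic5 (-1.68 ± 0.43, adjusted p = 0.0117) fell.

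In limma 1933 genes differed between the combined group and metformin, 1148 higher and 785 lower, 1363 by at least 1.5-fold. Of these 59.4% were higher, but 47.4% of the 1937 called after quantile normalization. The fixed genes that did not pass numbered 8, from -0.76 to 1.48 (lowest adjusted p = 0.053). The count was 1007 with the negative-control covariate, 499 without arrays 2 and 4, 1021 with the compared arrays alone and 1138 without combined mouse 4. The 1933 genes kept 83.6% of their median change with the covariate and 78.2% without the 2 arrays. Control signals shifted here too, by 0.153 for the positive controls, -0.241 for the poly-A spikes and -0.328 for the hybridization spikes. Their exact permutation p were 0.0159, 0.0238 and 0.0317 (adjusted p = 0.053, 0.0576 and 0.0576 over 20 tests). The unfolded protein response was called with the covariate (camera adjusted p = 9.28e-05) and without arrays 2 and 4 (0.00012), but not with an estimated correlation (0.991). With the covariate the limma calls of Creld2 (-1.82, adjusted p = 0.0597), Asic5 (-1.15, 0.0537), Hmox1 (1.22, 0.0514) and Fasn (1.19, 0.123) were lost. The number of lists called was 2 or 3 without metformin mouse 1, 2, 4 or 5 or combined mouse 2 or 3, and 5 without combined mouse 4 or 5. Without arrays 2 and 4, 9 of the 15 named genes that passed did not: Fam25c (0.0607), Hsph1 (0.117), Fabp7 (0.107), Creld2 (0.134), Asic5 (0.0775), Hspa5 (0.073), Pdia6 (0.0728), Hmox1 (0.0973) and Fasn (0.188). Their differences were then 1.35, -1.52, -1.22, -1.64, -1.07, -0.69, -0.81, 1.21 and 1.18 in that order. Egr1 was lost without metformin mouse 4 (0.0593). Fasn was lost without metformin mouse 2 (0.0841), 3 (0.0623) or 5 (0.104) or combined mouse 1 (0.0514), 2 (0.098) or 4 (0.0585), and Hmox1 was lost without most single mice of both groups (highest adjusted p = 0.114, without metformin mouse 4).

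The interaction asks whether the metformin difference under PM2.5 was unlike that without PM2.5. Among the genes that passed, the 5 largest by size, which the rule names, were lipid genes. The metformin difference was higher under PM2.5 by 3.32 ± 0.64 for Fasn (adjusted p = 0.03, limma, n = 5 mice per group), 3.20 ± 0.61 for Pnpla3 (adjusted p = 0.03), 3.02 ± 0.55 for Angptl8 (adjusted p = 0.0224) and 2.82 ± 0.57 for Acly (adjusted p = 0.0375). It was lower for Angptl4, at -2.81 ± 0.54 (adjusted p = 0.03). Both metformin means of Pnpla3, 3.65 and 3.82, lie below the mean negative-control median of 4.49, so the floor of the signal limits how far it could fall under PM2.5, and the size of its interaction is not measured. The sign follows from the group means. Without PM2.5 Fasn fell with metformin by 3.75, and its difference under PM2.5, where it was lower to begin with, did not pass. Of 20 lipogenesis genes 5 passed, all positive, and 12 adjusted over the list alone, with a median of 0.87 (camera adjusted p = 1.11e-12; adjusted p = 0.195 with an estimated correlation). All 19 cholesterol synthesis genes were above 0 with a median of 1.19, 0 passing in limma and 3 adjusted over the list alone (camera adjusted p = 1.93e-07; adjusted p = 0.856 with an estimated correlation). Complex I (median 0.30, camera adjusted p = 4.4e-05; adjusted p = 0.73 with an estimated correlation) and complexes II to V (0.25, adjusted p = 0.0058; adjusted p = 0.856 with an estimated correlation) were positive as well. Negative medians were found for glucocorticoid targets (-0.57, 1 passing and 4 adjusted over the list alone; camera adjusted p = 1.64e-05; adjusted p = 0.195 with an estimated correlation) and for 3 other lists. They were PPAR-alpha genes (-0.43, adjusted p = 6.55e-07), macrophage markers (-0.72, adjusted p = 1.31e-05) and the unfolded protein response (-0.44, adjusted p = 0.00288, or 0.0654 without metformin mouse 3). These 3 were not called with an estimated correlation (adjusted p = 0.856 for each). In these 3 lists and those of the respiratory complexes 0 members passed in limma; adjusted over the list alone 1 PPAR-alpha gene and 1 unfolded protein response gene did. All 8 lists stayed called without arrays 2 and 4 of the combined group, but the medians of 3 moved by more than 1.5 times, to -0.23 for PPAR-alpha genes, -1.08 for glucocorticoid targets and -0.44 for macrophage markers.

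In limma 22 genes showed an interaction, 19 positive and 3 negative, against 1545 at an unadjusted p under 0.05. Naming by size passes over genes that were higher in the combined group alone, whose interaction is not given here. Synrg had means of 7.51 in filtered air, 7.59 with metformin, 7.51 with PM2.5 and 9.32 in the combined group. Ptprf had 9.32, 9.41, 9.30 and 11.11 in the same order. Of the 40 lists 4 were called higher and 4 lower, 0 with an estimated correlation and 2 with fry. The other 32 had adjusted p from 0.118 to 0.968. The gene count was 44 with the negative-control covariate, 10 without arrays 2 and 4 and 108 with array weights. It was 14, 11 and 8 without filtered-air mice 2, 3 and 5, 8, 7 and 11 without metformin mice 2, 3 and 5, 7 without PM2.5 mouse 1 or 2, and 12 and 289 without combined mice 4 and 5. The 5 named genes all lost their call without PM2.5 mouse 1 (adjusted p from 0.0727 to 0.0945) or PM2.5 mouse 2 (0.0557 to 0.0953), metformin mouse 2 (0.0521 to 0.0576), metformin mouse 3 (0.0581 to 0.0748) and filtered-air mouse 5 (0.0505 to 0.0741). Without arrays 2 and 4 of the combined group Fasn (adjusted p = 0.0852), Pnpla3 (0.0698), Acly (0.0698) and Angptl4 (0.0621) lost theirs, with differences still at 3.07, 3.17, 2.73 and -2.52.

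Whether genes that moved with PM2.5 moved back with metformin was asked across all 11844 genes. The fold changes of PM2.5 against filtered air and of the combined group against PM2.5 correlated at 0.1, or at -0.069 with the negative-control covariate, where the shared PM2.5 arrays alone gave -0.497 in simulated data (range -0.784 to -0.154) and splitting those arrays gave a mean of 0.188 (-0.083 to 0.391). Of the 612 genes called with PM2.5, 264 (43.1%) had the opposite sign with metformin added. Of these 43 were also called: 23 that rose with PM2.5 and then fell (14.9 expected by chance) and 20 that fell and then rose (20.6 expected). Another 56 genes were called with the same sign, 40 rises (22 expected) and 16 falls (14 expected). These expectations take the comparisons as independent, whereas the shared PM2.5 arrays favour opposite signs, so no excess can be read from the counts of opposite sign. In a further comparison, of the combined group with filtered air, 4136 genes were called. They held 502 of the 612 genes with the same sign as with PM2.5, although the shared filtered-air arrays favour the same sign there. The response to PM2.5 without and with metformin, which shares no arrays, correlated at 0.469 (simulated range -0.456 to 0.431), with 114 shared rises where 30.6 were expected by chance and 92 shared falls where 19.6 were. The response to metformin without and with PM2.5 correlated at 0.438 (simulated range -0.479 to 0.431), with 43 shared rises (10.4 expected) and 39 shared falls (10.6 expected). Genes vary together, so with no effect the overlaps can lie far from these expectations. Both of these correlations lay only just above their simulated ranges, so the counts should not be read as stronger.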

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

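The tests with the negative-control covariate on the macrophage genes, with other pairs of arrays left out and with the fasting-induced genes were chosen after the results were seen, as were the 2 arrays left out and the comparison of control probe sets between the combined group and filtered air.

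The interaction of PM2.5 and metformin, a test of the difference between responses, passed for 22 genes. The 5 largest by size were Fasn (3.32), Pnpla3 (3.20), Angptl8 (3.02), Acly (2.82) and Angptl4 (-2.81) on the log2 scale. Without arrays 2 and 4 of the combined group all of these but Angptl8 lost their call (adjusted p from 0.0621 to 0.0852), though Fasn, Pnpla3, Acly and Angptl4 stayed at 3.07, 3.17, 2.73 and -2.52. All 5 lost their call without PM2.5 mouse 1 or 2, metformin mouse 2 or 3, or filtered-air mouse 5. Pnpla3 lay below the negative-control median in both groups on metformin, so the size of its interaction is not measured. The list medians of the interaction were 0.87 for lipogenesis, 1.19 for cholesterol synthesis, 0.30 for complex I, 0.25 for complexes II to V, -0.43 for PPAR-alpha genes, -0.44 for the unfolded protein response, -0.57 for glucocorticoid targets and -0.72 for macrophage markers. With an estimated correlation none of the 8 lists was called (adjusted p from 0.195 to 0.856). The medians of PPAR-alpha genes, glucocorticoid targets and macrophage markers moved by more than 1.5 times without arrays 2 and 4, to -0.23, -1.08 and -0.44. Of the negative-control probe sets, which no comparison of genes uses, the median was 0.184 higher in the combined group than in filtered air (exact permutation p = 0.00794; adjusted p = 0.0318 over 20 tests). The positive controls were 0.27 higher and the poly-A spikes differed by -0.50, with the same exact permutation p and adjusted p, so other control signals shifted too. With PM2.5 the poly-A spikes also differed by -0.50 from filtered air (exact permutation p = 0.0238; adjusted p = 0.0576 over 20 tests).

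Lipogenic genes were lower with PM2.5 and with metformin (list medians -0.76 and -1.60; camera adjusted p = 0.437 and 0.0264 with an estimated correlation), and the interaction was positive for Fasn and Acly. Both comparisons use the same filtered-air mice. Those arrays were split so that each comparison had its own. Across the 20 lipogenic genes the correlation of the fold changes then stayed between 0.803 and 0.925 in 20 splits. This argues against noise of single shared arrays as the source. A trait common to all filtered-air mice would stay in both parts, so the split cannot test it. A fasted-like state of the treated mice is a candidate explanation. The median of 9 fasting-induced genes was 1.06 with PM2.5 and 0.835 with metformin, with 5 and 4 called higher and 0 lower. Genes already seen to rise, such as Angptl4, Cpt1a and Pck1, were among the 9. A high median was thus partly built in and decides nothing. The PPAR-alpha and fatty acid oxidation list, fixed before the data were examined, had lower medians of 0.19 and 0.24. Pdk4, one of the 9, was at 1.66 with PM2.5 and -1.26 (adjusted p = 0.0902) with metformin, and Fgf21 did not pass in either (lowest adjusted p = 0.224). The labels give no food intake or body weight, so a fasted-like state and a direct action of PM2.5 or metformin cannot be told apart, and the direct action stays open, untested.

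More genes differed between the combined group and PM2.5 (1383) than between PM2.5 and filtered air (612). Without arrays 2 and 4 of the combined group, which had the highest negative-control signal, 206 genes were called against PM2.5, 199 of them among the 1383 and with the same sign, while 938 were called for PM2.5 in that fit, so these 2 arrays may account for part of the count, although the 1383 genes kept 74.2% of their median change. With the negative-control median as a covariate 79 genes were called. The 1383 genes kept 68.5% of their median change, which leaves the background as the cause undecided. The macrophage markers kept 46.3% of theirs, so background may account for part of their fall, although the list was still called at the preset correlation. At an estimated correlation, without the covariate, that list was not called (camera adjusted p = 0.81). The loss of arrays as such cannot be told apart from these: leaving out 2 and 4 was the only 1 of 10 pairs of the combined group to give a count of 206 or lower, but the next lowest pair gave 278, with a median of 923 and a highest count of 2506. A stronger response to metformin under PM2.5 in mice 2 and 4 stays open, untested, since 5 mice cannot separate it from array background.

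The samples were split 100 times into groups of the same sizes, the real split included. Only the real split (1 of 100) gave as many genes in each comparison. This is the lowest share that 100 splits can give, so chance is made unlikely for each count but not excluded. Splits also cannot separate a treatment from array background that differs between groups. The real count and the highest of the other splits were 612 and 280 for PM2.5 against filtered air, 373 and 1 for metformin against filtered air, 1383 and 993 for the combined group against PM2.5, 1933 and 685 for the combined group against metformin, and 22 and 1 for the interaction. The first principal component held 31.7% of the variance, with combined arrays 2 and 4 at 55.5 and 55.1, the highest of all arrays.

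Single mice stood apart from the other 4 of their group when the gap to the nearest mouse was more than 0.71 of the group's range, which chance gives in about 1 in 20 groups. This was so in 3 of 48 tests of array measures (6.25%) and 20 of 352 tests of named genes (5.68%). For array measures the values were 0.813 for the positive controls of metformin mouse 2 (low), 0.737 for the poly-A spikes of metformin mouse 4 (low) and 0.722 for the unfolded protein response of filtered-air mouse 1 (high). In filtered air they were 0.794 for Angptl4 in mouse 1 (low), 0.76 for Creb3l3 in mouse 3 (high), 0.749 for Sgk1 in mouse 5 (high), and in mouse 4 0.854 for Mid1ip1 (low), 0.852 for Aacs (low), 0.778 for Adgre1 (high) and 0.877 for Itih4 (high). With metformin they were 0.757 for Ndufb3 in mouse 1 (low), 0.793 for Foxo1 in mouse 5 (high), and in mouse 4 0.85 for Angptl8 (high), 0.766 for Uqcr10 (low), 0.757 for Atp5l (low) and 0.726 for Steap4 (low). In the combined group they were 0.718 for Creld2 and 0.773 for Asic5 in mouse 2 (both low), 0.756 for Zbtb16 (high), 0.721 for Atp5l (high) and 0.775 for Steap4 (low) in mouse 3, and 0.831 for Mid1ip1 and 0.799 for Gstm6 in mouse 4 (both low).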

How the results depend on the processing

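The negative-control covariate and the fit without arrays 2 and 4 of the combined group were chosen after the data were seen. The negative-control median varied most in the combined group (SD 0.147, against 0.031 to 0.072 in the others), where arrays 2 and 4 were highest. Both fits thus lean on the same arrays and are not separate checks. No named gene or called list changed direction under any alternative. A value reversed once: the correlation between the PM2.5 response and the metformin response under PM2.5, 0.1 with all arrays, was -0.069 with the negative-control covariate; the cause was not tested. Gene counts moved by more than 1.5 times as follows, causes not tested unless the fit held fewer arrays. With array weights they were 1376 for PM2.5 against filtered air, 854 for metformin against filtered air and 108 for the interaction. With the covariate they were 147 for metformin against filtered air, 79 and 1007 for the combined group against PM2.5 and against metformin, and 44 for the interaction. Without arrays 2 and 4 they were 938 for PM2.5 against filtered air, 206 and 499 for the combined group against PM2.5 and against metformin, and 10 for the interaction. With only the arrays compared they were 509 and 1021 for those same comparisons of the combined group; the interaction uses all arrays and has no such value.

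Lists called depended on the test of the lists. With an estimated correlation, which widens the test where members vary together, the counts were 0 for PM2.5 against filtered air, 1 for metformin, 0 and 0 for the combined group against PM2.5 and against metformin, and 0 for the interaction. With fry they were 10 for metformin, 1 and 0 for the combined group, and 2 for the interaction. Fry asks whether members move on balance 1 way, not whether they move more than other genes. Without a filter on dim genes 19 lists were called for PM2.5 against filtered air and 6 for the combined group against metformin. In the latter, 5 were called with quantile normalization, 4 with the covariate and 4 without arrays 2 and 4, against 1 in the fit reported.

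Leaving out each mouse in turn gave 208 to 759 genes for PM2.5 against filtered air (lowest without PM2.5 mouse 2, highest without combined mouse 5), 157 to 487 for metformin against filtered air (metformin mouse 3, combined mouse 5). It gave 637 to 2143 and 1138 to 2407 for the combined group against PM2.5 and against metformin (combined mice 4 and 5 in both). It gave 7 to 289 for the interaction (7 without metformin mouse 3 or PM2.5 mouse 1 or 2, 289 without combined mouse 5). The lists called ranged over 11 to 14, 12 to 18, 3 to 11, 1 to 5 and 7 to 11 in the same order. The correlations ranged from 0.423 to 0.49 for PM2.5 without and with metformin, 0.382 to 0.487 for metformin without and with PM2.5, 0.038 to 0.148 for PM2.5 and metformin under PM2.5, and 0.543 to 0.644 for PM2.5 and metformin.

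The filters, the other normalizations, the other ways to combine probe sets and eBayes with trend and robust options kept every gene count within 1.5 times. No paired analysis was possible because the labels give no shared replicate numbers. A covariate of 3' against 5' control signal, leaving out cross-hybridizing probe sets and a pseudocount were not run, since the array and the log2 scale gave nothing to apply them to. Signal over background limits dim genes: 44% of tested genes had a mean above 8.36, the mean 95th percentile of the negative controls.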

Other observations

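The genes of the first paragraphs were chosen after their values were seen, from lists fixed earlier, and so were the clock test and the overlap of PM2.5 and metformin responses.

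Some circadian genes changed with metformin, although the clock list of 17 tested genes was called in no comparison (adjusted p = 0.0708 for metformin against filtered air). In that comparison 3 of the 17 rose, 2 fell and 12 did not pass. Without PM2.5 the clock activator Arntl fell with metformin from 9.17 ± 0.29 to 7.60 ± 0.56 (SD, n = 5), a difference of -1.57 (adjusted p = 0.0019, limma). Its partner Npas2 fell by 1.09 (adjusted p = 0.0379). The output genes Dbp (1.54, adjusted p = 0.0118), Hlf (0.80, adjusted p = 0.0372) and Usp2 (2.34, adjusted p = 0.0034) rose, and Per3 was at 1.33 (adjusted p = 0.0863). Of the others that did not pass, Ciart was at 2.09 (adjusted p = 0.0596), Per1 at 0.80 (0.328) and Nr1d2 at 0.56 (0.101). Nfil3 (-0.40), Per2 (0.40), Bhlhe41 (0.33), Cry2 (0.20), Clock (-0.15), Cry1 (-0.10), Bhlhe40 (-0.08) and Nr1d1 (-0.05) differed by less. The metformin mean of Npas2 (4.42) and the filtered-air mean of Usp2 (4.12) lie below the mean negative-control median of 4.49, so the sizes of their changes are not measured. For Arntl, Npas2, Dbp, Per3 and Usp2, 5 of 5 metformin mice lay beyond every filtered-air mouse. Under PM2.5, metformin again went with lower Arntl (-0.96, adjusted p = 0.0221) and Npas2 (-0.90, adjusted p = 0.0427) and higher Dbp (1.89, adjusted p = 0.00153) and Per3 (1.66, adjusted p = 0.015), while Usp2 was at 1.13 (adjusted p = 0.0817). PM2.5 went with higher Arntl both without metformin (1.09, adjusted p = 0.0196) and with it (1.70, adjusted p = 0.000583).

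Iron, insulin and bile acid genes changed singly, in lists that were not called. Tfrc, the transferrin receptor that takes up iron, fell with PM2.5 by 2.24 ± 0.29 (adjusted p = 0.000279, limma) and with metformin by 1.42 ± 0.29 (adjusted p = 0.00975), and Alas1, the first enzyme of heme synthesis, rose by 0.88 ± 0.25 (adjusted p = 0.045) and 1.15 ± 0.25 (adjusted p = 0.0164). The hepcidin genes Hamp (0.84, adjusted p = 0.0171) and Hamp2 (0.83, adjusted p = 0.0184) and the ferritin gene Ftl1 (0.66, adjusted p = 0.0104) were higher in the combined group than with metformin. The insulin receptor gene Insr rose with PM2.5 (0.64, adjusted p = 0.0369) and was higher in the combined group than with PM2.5 (0.81, adjusted p = 0.00604) or metformin (0.93, adjusted p = 0.0019). Irs2, which carries the insulin signal, rose with PM2.5 (1.06, adjusted p = 0.0258), and Irs1 was higher in the combined group than with metformin (1.03, adjusted p = 0.0111). The bile salt exporter gene Abcc3 was higher in all 4 comparisons between groups, by 0.92 with PM2.5 (adjusted p = 0.00351), 0.64 with metformin (adjusted p = 0.0392), and 0.54 and 0.82 in the combined group against PM2.5 and metformin (adjusted p = 0.0411 and 0.00336).

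A difference in the hour of tissue collection is a candidate explanation for the clock genes. The median change of Arntl and Npas2 minus that of Dbp, Per3 and Usp2 was -2.87 for metformin against filtered air and -2.59 for the combined group against PM2.5. These genes were chosen for the directions they showed, so the value restates the pattern and decides nothing. Per mouse, the mean log2 level of Arntl and Npas2 minus that of Dbp, Per3 and Usp2 ran from -1.60 to 0.11 in filtered air. With metformin it ran from -5.40 to -3.09, without overlap. Each of these genes already separated those groups in every mouse, so no overlap could have resulted. The ranges did overlap under PM2.5, from -1.37 to 0.978 without metformin and from -4.43 to -1.045 in the combined group. The labels give no collection time, so an hour that differed by group and an action of metformin on the clock cannot be told apart, and the latter stays open, untested.

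The responses to PM2.5 and to metformin, each against filtered air, correlated at 0.591 across the 11844 genes. Simulated data with no effect gave 0.513 (range -0.058 to 0.801), where the shared filtered-air mice alone produce the correlation. With those mice split between the comparisons the mean was 0.397 (0.313 to 0.515). The comparisons shared 58 rises where 3.98 were expected by chance and 67 falls where 5.6 were, without allowing for the shared mice or for genes that vary together.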
